A study of Mus musculus with 8 samples.

How the data were processed

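Hearts of mice at postnatal day 40 were profiled by bulk RNA sequencing in 3 genotypes: wild type (n = 2), heterozygous (n = 3) and homozygous (n = 3) for a deletion of a conserved enhancer of Actn2. Per the labels, the hearts came from the same litter, RNA was taken with Trizol and libraries were sequenced on a HiSeq 2500. The deposited values are raw counts per gene symbol for 24516 genes, 1 column per library, with no normalization. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2, Subread, featureCounts and DESeq2 were used, on the mm10 build. The annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Gene identifiers, positions, transcript lengths, 3' UTR lengths and GC content were taken from GENCODE vM21, in which 98.5% of the symbols were found.

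Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 on genotype, which left 15075 genes (61.5%), and were scaled by TMM. All 8 libraries entered 1 robust quasi-likelihood fit of edgeR, since the wild type has only 2 libraries. The 3 pairwise comparisons, the mean of both deletion genotypes against wild type, and a slope on the number of deleted alleles were tested by the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are TMM-scaled CPM (counts scaled to a library of 1e6) with the SD between libraries, and fold changes are log2 with the standard error (SE) of the fit. Libraries held 22230090 to 55902737 counts. A group of libraries all at 0 was given a floor of 3 counts over the group, which covers counting error only. The p-values measure spread between the samples. Each gene has 1 spread for all genotypes, which rests mostly on the deletion libraries. The wild-type libraries differed more from each other (r = 0.952) than pairs of deletion libraries did (0.969 to 0.982). Adjusted p-values against wild type can therefore be too small. The labels do not say more about separate animals than that the hearts share a litter.

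Gene lists and cell type markers were fixed before the data were examined, as were the tests and the first set of alternatives. Some lists share members: the atrial markers Myl4, Myl7, Sln and Nppa are also in the list of fetal and stress genes. Each list with at least 2 measured members (38 lists) was tested on log2 CPM (prior count 2) by camera of limma 3.58.1 with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. The thymus markers had 1 measured member, and no mitochondrially encoded gene was in the table, so neither list was tested. The rule for named genes was also fixed then: Actn2 and its flanking genes, the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 1 CPM and a regular symbol (or, if none passes, the 3 smallest p in each direction, as values), up to 4 members of each list by smallest p, a panel of 18 heart genes, and sex-linked and clock genes. The first 2 members by p of each list were followed through every alternative, with all flanking genes, the panel and the largest changes. For homozygous against heterozygous only the 6 genes with the smallest p were followed. Both limits were set after the values were seen, by rank alone. Of the genes this rule picks, 2 are not named or followed here, with no gene put in their place; the list tests and gene counts include them.

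Alternatives covered scaling (DESeq2 size factors, total counts, abundant genes left out), filtering, tool (DESeq2 1.42.0 and limma-voom), a fit that is not robust, only the groups compared, the replicate number as a block, a term for sex, and each library left out. Leaving out a wild-type library leaves 1 of that genotype, so the spread then comes from the deletion groups alone. Fold changes of the deletion genotypes followed gene properties, so a correction was added after the data were seen: in each library the deviation from the mean log2 CPM was fitted by splines (4 df each) of transcript length, 3' UTR length and GC content, and removed as an offset, for the 14171 genes with all 3 properties. This correction was also combined with leaving out wild type 2 and with the sex term. The fit was tested on simulated counts with 200 changed genes: of 50 genes changed 2-fold, 42% were recovered for homozygous against wild type, 34% for heterozygous against wild type and 58% for homozygous against heterozygous, with 9, 9 and 12 false calls. These counts had the same spread in all genotypes and no trend with gene properties, unlike the real libraries. They therefore do not give the recovery or the false calls of the real comparisons. The correction was tested on simulated counts with a set trend in the wild-type libraries, linear in GC content and log2 3' UTR length, and none in transcript length. Calls among unchanged genes went from 5193 to 9 and 86% of 4-fold genes were called. The splines can fit such a trend, so this test does not say how well they remove the bias of the real libraries.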

Results

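Gene expression was measured in 8 hearts of 40-day-old mice by bulk RNA sequencing: 2 wild type, 3 heterozygous and 3 homozygous for the enhancer deletion. Libraries held 25017723 and 30568468 counts in wild type 1 and 2. They held 22230090, 31247412 and 28814687 counts in heterozygous 1 to 3, and 33197075, 55902737 and 34593519 counts in homozygous 1 to 3. Xist, the RNA that coats the inactive X chromosome, was high in 4 libraries (heterozygous 2 and 3, homozygous 2 and wild type 2) and low in the other 4, so both sexes were present in every genotype. The first principal component of the 1000 most variable genes held 35.9% of the variance and set wild type 2 (61.4) apart from wild type 1 (10.8) and from the 6 deletion libraries (-14.2 to -7.87). Across genes, wild type 1 and wild type 2 correlated at r = 0.952, and pairs of deletion libraries at 0.969 to 0.982. Wild type 1 correlated with the deletion libraries at 0.957 to 0.966, above its value with wild type 2, and wild type 2 with them at 0.927 to 0.935. Genes are not independent replicates.

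Actn2 encodes alpha-actinin 2, the actin cross-linker of the sarcomeric Z-disc, and is the gene whose enhancer was deleted. Its level (ENSMUSG00000052374.16, chromosome 13, 12269426 to 12340760, minus strand, mm10) was 2187 and 2703 CPM in the wild-type hearts, 1693, 1546 and 1638 CPM in the heterozygous hearts, and 2115, 1611 and 1791 CPM in the homozygous hearts. Actn2 fell in heterozygous hearts to 1626 ± 74.4 CPM (SD, n = 3) from 2445 ± 365 CPM (SD, n = 2), a log2 fold change of -0.59 (SE 0.16, adjusted p = 0.0193). Homozygous hearts had 1839 ± 256 CPM (SD, n = 3), a log2 fold change of -0.41 (SE 0.16) that did not pass the test (adjusted p = 0.0771). Homozygous against heterozygous, the log2 fold change was 0.18 (SE 0.14, adjusted p = 0.9996). The heterozygous call was lost without heterozygous 2 (-0.55, adjusted p = 0.0725) or heterozygous 3 (-0.59, adjusted p = 0.0595). It was also lost in a fit of only the groups compared (adjusted p = 0.0536), with the replicate number as a block (-0.59, adjusted p = 0.0546), and after the correction for gene properties (-0.27, adjusted p = 0.237). Without wild type 2, which leaves 1 wild-type library, the value was -0.40 and the call was lost too. The homozygous difference passed without wild type 1 (-0.55, adjusted p = 0.0200) and with DESeq2 (-0.41, adjusted p = 0.0375), and was -0.08 after the correction.

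**Figure D1:**
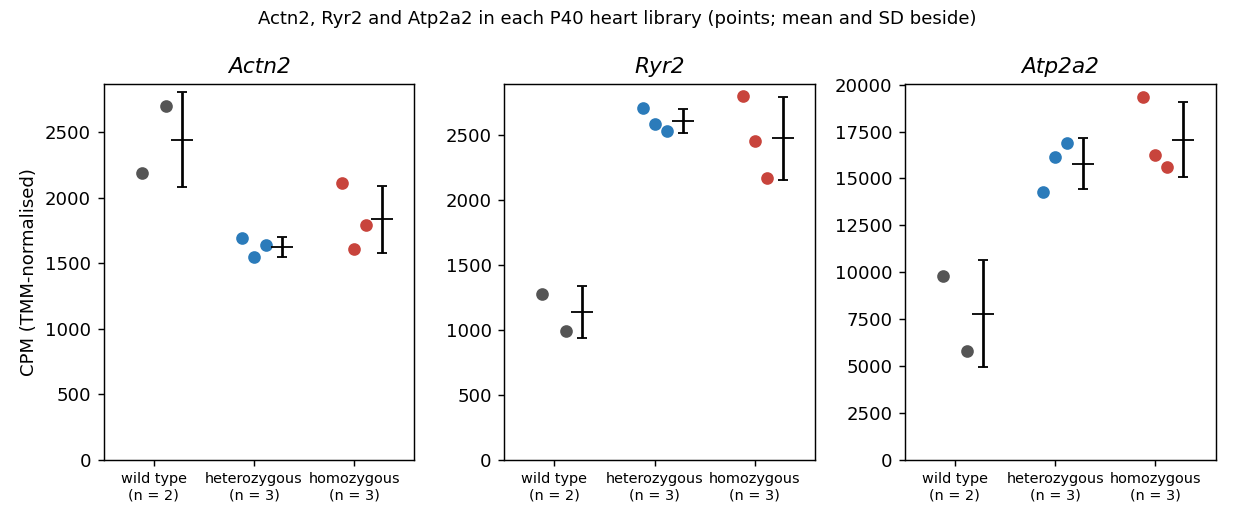
Actn2, Ryr2 and Atp2a2 in each library: the y axis is TMM-scaled CPM, points are libraries grouped by genotype, and the bar beside each group is the mean with its SD. Ryr2 was 1133 CPM on average in wild type and 2603 and 2471 CPM in the heterozygous and homozygous hearts.

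Among the 11 measured genes of the list around Actn2, Ryr2, the calcium release channel of the sarcoplasmic reticulum (chromosome 13, 11553102 to 12106945), rose in both deletion genotypes. Its level was 1133 ± 199.8 CPM in wild type (SD, n = 2), 2603 ± 91.6 CPM in heterozygous and 2471 ± 317 CPM in homozygous hearts (SD, n = 3 each), which is 2.30-fold (adjusted p = 0.000896) and 2.18-fold (adjusted p = 0.00133) of wild type. After the correction the log2 fold changes were 0.65 and 0.56 (adjusted p = 0.0154 and 0.0261). Mtr, methionine synthase, rose by 1.17 and 1.07 in log2 units in heterozygous and homozygous hearts (adjusted p = 0.0109 and 0.0158). Lyst, a regulator of lysosomal trafficking, rose by 0.86 and 0.82 (adjusted p = 0.00317 and 0.00416). Neither rise held after the correction, and that of Mtr was lost without wild type 2 (0.90 and 0.81, adjusted p = 0.104 and 0.145). The others did not pass: homozygous and heterozygous log2 fold changes were -0.18 and 0.00 for Heatr1, 0.13 and 0.13 for Lgals8, -1.81 and -1.72 for Edaradd, and 0.12 and 0.02 for Ero1lb. They were -0.46 and -0.41 for Gpr137b, 0.48 and 0.41 for Nid1, and 0.18 and -0.67 for Chrm3. Nid1 passed in both once wild type 1 was left out (1.02 in homozygous and 0.96 in heterozygous hearts, adjusted p = 0.00120 and 0.00174). Ero1lb changed sign without wild type 2 (-0.0124 and -0.12) and, in heterozygous hearts, without heterozygous 3 (-0.0586), and Heatr1 in heterozygous hearts without heterozygous 2 (-0.0438) or wild type 1 (-0.00487). The list had 3 higher and 0 lower genes in homozygous hearts and 3 higher and 1 lower, Actn2, in heterozygous hearts, the same over all genes and adjusted over the list alone, and the list test did not pass (adjusted p = 0.484 and 0.769).

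Homozygous against wild type asks what follows the loss of both enhancer copies. Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose from 7798 ± 2856 (SD, n = 2) to 17065 ± 1996 CPM (SD, n = 3, log2 fold change 1.13, SE 0.22, adjusted p = 0.00494), its inhibitor Pln rose by 0.78 (SE 0.14, adjusted p = 0.00335). The sodium-calcium exchanger Slc8a1 rose by 1.74 (SE 0.16, adjusted p = 0.000148). Myl7 and Myl4, the atrial myosin light chains, fell by 5.23 and 3.19 in log2 units (SE 0.49 and 0.47, adjusted p = 0.000157 and 0.00151). Of 78 cytosolic ribosomal protein genes 58 fell (list test adjusted p = 7.73e-12, and adjusted p = 0.674 with an estimated correlation), and 21 of 76 after the correction. In all, 4180 of 15075 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2308 higher and 1872 lower, and 1217 of them changed at least 2-fold. The count was 2564 without homozygous 3, and 1997 of 14171 genes (1184 higher and 813 lower) after the correction. The correction called 1480 of the same genes in the same direction, and 1 further gene with the opposite sign. Without wild type 2, in a fit with 1 wild-type library, the count was lower too, mostly by loss of lower genes.

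Among the 10 largest rises in homozygous hearts were Zfp536 (log2 fold change 3.75), Chrm2 (3.67), Nt5c1a (3.60), Eps8l1 (3.49), Lmbrd2 (3.27), Nebl (3.22), Pdpr (3.21), Hipk2 (3.16) and Hist1h1e (3.15). Chrm2, the cardiac muscarinic acetylcholine receptor, rose with an SE of 0.27 (adjusted p = 6.47e-05). Nebl, a nebulin-like protein of the Z-disc, went from 26.0 ± 9.84 CPM (SD, n = 2) to 243 ± 25.7 CPM (SD, n = 3, adjusted p = 4.97e-05). The largest falls were Sln (-6.42), Cfd (-5.49), Myl7 (-5.23), Cnn1 (-3.51), Susd5 (-3.48), Myl4 (-3.19), Wif1 (-2.95), Dkk3 (-2.92), Comp (-2.82) and Chad (-2.80). Comp, a cartilage matrix protein, went from 18.7 ± 2.05 to 2.64 ± 0.469 CPM (adjusted p = 0.000294). Without wild type 2, the values for Eps8l1, Cfd, Cnn1 and Wif1 were 2.89, -2.94, -2.48 and -3.56 and no longer passed (adjusted p = 0.193, 0.228, 0.0560 and 0.0597). Eps8l1 also failed without homozygous 1 or 2 (adjusted p = 0.0593 and 0.0848), Hist1h1e without homozygous 2 or 3 (3.11 and 2.97, adjusted p = 0.0562 and 0.0690), and Wif1 without homozygous 1, homozygous 3 or wild type 1 (-2.60, -2.64 and -1.75, adjusted p = 0.0756, 0.0918 and 0.191); DESeq2 did not call Sln (adjusted p = 0.0767).

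Sarcomere lists moved in both directions in homozygous hearts before the correction. After it, thick filament genes had 4 rises and 3 falls, thin filament genes 5 and 2, and Z-disc and costamere genes 9 and 2. The counts that follow are those before the correction. Of 21 thick filament genes 6 rose and 5 fell (adjusted over the list alone 6 and 6, list test adjusted p = 0.817). Of 22 thin filament genes 5 rose and 5 fell (alone 5 and 6, adjusted p = 0.916); Nebl and the actin nucleator Fhod3 (1.04, SE 0.18) rose. This list's median (-0.05) and mean (-0.17) were negative while its test pointed up. Of 47 Z-disc and costamere genes 12 rose and 7 fell (alone 12 and 7, adjusted p = 0.348), with rises of Sgcd, delta-sarcoglycan (2.52, SE 0.14), and Dmd, dystrophin (1.90, SE 0.14). Among the other actinins, Actn1 fell by 0.70 (SE 0.13, adjusted p = 0.00358), and Actn4 had a log2 fold change of -0.27 (adjusted p = 0.158). In the panel of heart genes, Myh7 was at -0.68 (adjusted p = 0.0228) and Tnni3, cardiac troponin I, at -0.76 (adjusted p = 0.0171). Both calls depended on single libraries: without wild type 2 they were -0.40 and -0.30 (adjusted p = 0.205 and 0.188). They were, without homozygous 1, -0.69 and -0.73 (adjusted p = 0.0638 and 0.0612). Without homozygous 3 Myh7 was -0.55 (adjusted p = 0.0862) and without homozygous 2 Tnni3 was -0.75 (adjusted p = 0.0535). Kcnj2, an inward rectifier potassium channel, rose by 1.76 (adjusted p = 0.0162) and was lost without wild type 2 (1.31, adjusted p = 0.131). Myh6 (-0.35), Nppa (-0.89), Nppb (-0.18), Acta1 (-1.30), Tnni1 (-3.42), Cacna1c (-0.08), Ppargc1a (0.78), Cpt1b (0.56) and Pdk4 (0.70) did not pass. Acta1 passed without heterozygous 1 (-1.28, adjusted p = 0.00548), and Tnni1 and Cpt1b without wild type 1 (-4.32 and 2.21, adjusted p = 0.0154 and 0.00147). The sign changed without wild type 2 for Nppb (0.75), Cacna1c (0.0592) and Cpt1b (-0.16), and without homozygous 2 for Nppb (0.0169).

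Among lists of heart function and metabolism, cardiac transcription factors and the TCA cycle passed the list test upward in homozygous hearts. After the correction, adult maturation, ion channels, fatty acid oxidation and mitochondrial dynamics passed upward too (adjusted p = 0.000981, 0.0415, 0.0042 and 0.0274). With an estimated correlation the adjusted p-values of that fit were 0.267, 0.531, 0.708 and 0.571. Of 31 transcription factors 12 rose and 4 fell (alone 15 and 4, adjusted p = 0.0117, and adjusted p = 0.389 with an estimated correlation), including Prox1 (1.93, SE 0.19) and the oestrogen-related receptor Esrrg (1.38, SE 0.14). Of 27 TCA cycle genes 8 rose and 1 fell (alone 10 and 4, adjusted p = 0.0368, and adjusted p = 0.674 with an estimated correlation), with Pdha1 of pyruvate dehydrogenase at 1.70 (SE 0.22) and Dld at 1.30 (SE 0.17). The TCA list call was lost without homozygous 1, homozygous 3 or wild type 2 (adjusted p = 0.0718, 0.0813 and 0.0624). Adult maturation genes had 13 rises and 5 falls of 44 (alone 14 and 5, adjusted p = 0.0674, and 0.0399, 0.0386 and 0.0442 without heterozygous 1, homozygous 2 or wild type 2). Calcium handling genes had 12 and 3 of 40 (alone 12 and 4, adjusted p = 0.0729), and ion channels 10 and 3 of 34 (alone 12 and 6, adjusted p = 0.145). Fatty acid oxidation had 11 and 4 of 49 (alone 11 and 4, adjusted p = 0.348). Mitochondrial dynamics had 13 and 2 of 32 (alone 14 and 3, adjusted p = 0.0913, and 0.0388 without homozygous 2), with a rise of Opa1, which fuses inner mitochondrial membranes (2.30-fold, adjusted p = 0.000568). Glycolysis had 1 and 5 of 29 (alone 1 and 5, adjusted p = 0.507, median 0.07, mean -0.14), among them Gapdh, which fell by 1.25 (SE 0.14), and the glycogen phosphatase subunit Ppp1r3a, which rose by 1.95 (SE 0.19). After the correction glycolysis had 4 rises and 2 falls (median 0.16, list test adjusted p = 0.288).

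Lower lists in homozygous hearts were led by cytosolic ribosomal proteins, of which 58 of 78 fell and 0 rose (alone 64 and 0, median -0.86, adjusted p = 7.73e-12, and adjusted p = 0.674 with an estimated correlation), for example Rpl6 (-0.87, SE 0.14). Oxidative phosphorylation had 42 falls and 3 rises of 84 (alone 53 and 4, median -0.59, adjusted p = 7.28e-08, and adjusted p = 0.674 with an estimated correlation), for example Atp5d of ATP synthase (-0.97, SE 0.16). Mitochondrial ribosomal proteins had 27 falls and 3 rises of 78 (alone 33 and 5, median -0.31, adjusted p = 0.00026, and adjusted p = 0.674 with an estimated correlation). After the correction the medians of these 3 lists were -0.41, -0.12 and -0.00, and the calls of the last pair were lost (adjusted p = 0.151 and 0.561). In that fit 21 cytosolic ribosomal protein genes fell and 0 rose (adjusted p = 6.08e-08, and adjusted p = 0.571 with an estimated correlation), and 6 oxidative phosphorylation genes fell and 5 rose. Mitochondrial ribosomal proteins then had 12 falls and 3 rises. Of 44 matrix genes 10 fell (alone 10, adjusted p = 0.00165, and adjusted p = 0.674 with an estimated correlation, without wild type 1 adjusted p = 0.239). Fmod, fibromodulin, was at -1.78 (SE 0.26). Of 28 immediate early genes 7 fell (alone 7, adjusted p = 0.00165, and adjusted p = 0.436 with an estimated correlation), with Klf2 at -1.28 (SE 0.20). After the correction 2 of them fell (median -0.34, adjusted p = 0.0298, and adjusted p = 0.531 with an estimated correlation). Of 39 interferon response genes 6 fell (alone 6, adjusted p = 0.00363, and adjusted p = 0.679 with an estimated correlation, without homozygous 3 or wild type 2 adjusted p = 0.0541 and 0.258). Of 29 fetal and stress genes 8 fell and 2 rose (alone 8 and 2, adjusted p = 0.0396, and adjusted p = 0.389 with an estimated correlation, without homozygous 1 or wild type 1 adjusted p = 0.0569 and 0.143, after the correction 0.0540).

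Markers of atrial cardiomyocytes were the marker group with the lowest median in both deletion genotypes. The falls of Myl4, Myl7 and Sln also count among the fetal and stress genes, so these lists are not independent. Myl4 and Myl7 are in the thick filament list too, and Sln in the calcium handling list. Of 9 measured, 5 fell and 0 rose in homozygous and in heterozygous hearts (alone 5 and 5, medians -2.50 and -1.93, adjusted p = 0.000348 and 0.000496, and adjusted p = 0.389 and 0.522 with an estimated correlation). Myl7 was 10.4 ± 5.41 CPM in wild type (SD, n = 2), 0.496 ± 0.208 CPM in heterozygous and 0.274 ± 0.0948 CPM in homozygous hearts (SD, n = 3 each), and Dkk3 25.6 ± 2.10, 3.31 ± 1.06 and 3.34 ± 1.32 CPM. Sln, sarcolipin, averaged 4.10 CPM in wild type and had no count in any heterozygous library, which at the floor of 3 counts over the group (0.0360 CPM) is at least 114-fold lower; the heterozygous median with Sln at that bound was also -1.93. After the correction the medians were -1.95 and -1.38 (adjusted p = 5.88e-05 and 0.000177, and adjusted p = 0.168 and 0.221 with an estimated correlation).

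**Figure D2:**
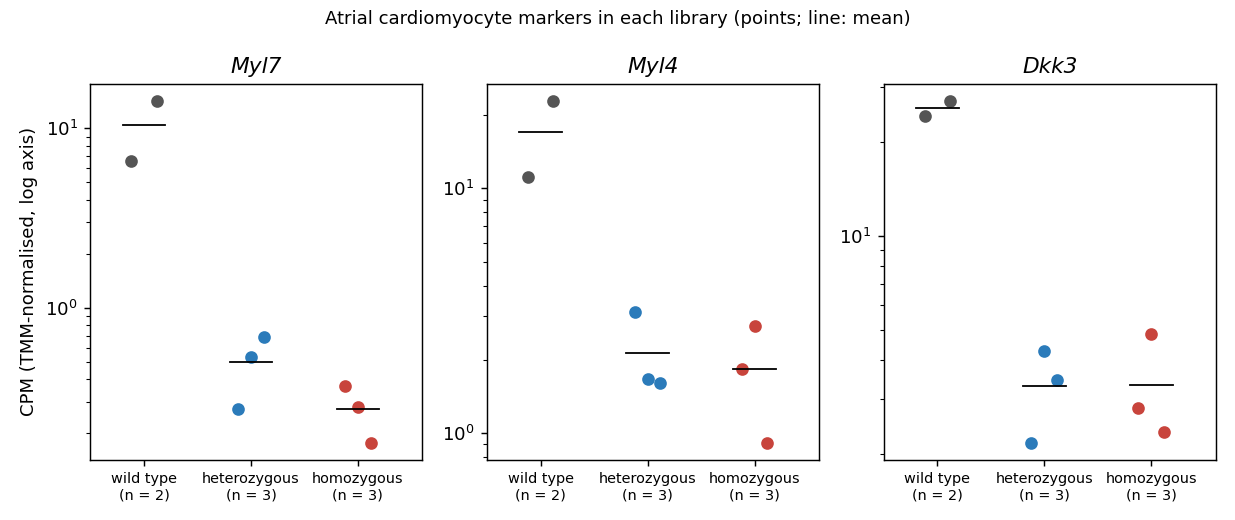
Atrial markers Myl7, Myl4 and Dkk3 in each library: the y axis is TMM-scaled CPM on a log scale, points are libraries grouped by genotype, and lines are means. Dkk3 averaged 25.6 CPM in wild type and 3.31 and 3.34 CPM in heterozygous and homozygous hearts.

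Markers of other cell types were given by the same tests, homozygous first and heterozygous second. Endothelial markers had 5 falls and 0 rises of 12 (alone 6 and 0), and 5 falls and 1 rise (alone 5 and 1), with adjusted p = 0.0368 and 0.0341, and adjusted p = 0.674 and 0.696 with an estimated correlation. Egfl7, an endothelial secreted factor, was at -0.96 (SE 0.16) in homozygous hearts. The endothelial calls were lost without wild type 1 (adjusted p = 0.0616 and 0.0640) or wild type 2 (0.0507 and 0.0597), the homozygous one also without homozygous 2 or 3 (0.0523 and 0.0827) and the heterozygous one without heterozygous 3 (0.0998). Smooth muscle and pericyte markers had 4 falls and 1 rise of 12 (alone 5 and 1, adjusted p = 0.0913), and 7 falls and 1 rise (alone 8 and 1, adjusted p = 0.0374, and adjusted p = 0.696 with an estimated correlation, without heterozygous 3, wild type 1 or wild type 2 adjusted p = 0.0881, 0.0682 and 0.0888). Fibroblast markers had 3 and 2 falls of 11 (alone 3 and 2, adjusted p = 0.0774 and 0.340, the first passed without homozygous 2 or wild type 2, at 0.0311 and 0.00584), with Gsn, gelsolin, at -1.03 (SE 0.18) in homozygous hearts. Cardiomyocyte markers had 2 rises and 2 falls, and 2 rises and 3 falls, of 10 (alone 2 and 3, and 2 and 5, adjusted p = 0.647 and 0.497). Macrophage markers had 2 rises and 2 falls, and 3 rises and 1 fall, of 12 (alone the same, adjusted p = 0.916 and 0.769). Adipocyte markers had 2 falls of 6 in each (alone 3 in each, adjusted p = 0.0815 and 0.227, the first 0.0491 without heterozygous 1). Endocardial and lymphatic markers had 1 rise and 1 fall, and 1 rise, of 8 (alone the same, adjusted p = 0.898 and 0.951). Skeletal muscle markers had 1 and 0 falls of 5 (alone 0 and 0, adjusted p = 0.297 and 0.340). Schwann and neuron markers had 1 and 2 falls of 7 (alone 0 and 2, adjusted p = 0.145 and 0.167, the second 0.0442 without homozygous 3). Mesothelial markers had 0 and 1 rises of 9 (alone 0 and 0, adjusted p = 0.458 and 0.383). After the correction 3 and 2 endothelial markers fell in homozygous and heterozygous hearts, and 3 smooth muscle markers fell in heterozygous hearts. The list tests were at adjusted p = 0.00585, 0.00726 and 0.00506, and adjusted p = 0.571, 0.726 and 0.726 with an estimated correlation. In the same fit the fibroblast, smooth muscle and adipocyte lists passed downward in homozygous hearts (adjusted p = 0.0186, 0.0274 and 0.0298, and adjusted p = 0.571, 0.571 and 0.531 with an estimated correlation). No member passed among lymphocyte and neutrophil markers (11 measured, adjusted p = 0.608 and 0.462), erythroid markers (5, 0.916 and 0.497) or lung markers (3, 0.458 and 0.383), over all genes or over the list alone.

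Heterozygous against wild type asks what 1 deleted copy is accompanied by. Atp2a2 rose to 15780.3 ± 1358 CPM (SD, n = 3, log2 fold change 1.02, SE 0.22, adjusted p = 0.00741), Pln by 0.91 (SE 0.14, adjusted p = 0.00144) and Slc8a1 by 1.75 (SE 0.16, adjusted p = 0.000137). The phosphodiesterase Pde3a, which degrades cyclic AMP, rose by 2.74 (SE 0.20, adjusted p = 4.98e-05). In all, 4219 genes passed, 2295 higher and 1924 lower, and 1228 changed at least 2-fold. The count was 2359 without wild type 2 (1640 higher and 719 lower), 2668 in a fit of only the groups compared, and 1899 (1099 higher and 800 lower) after the correction, which called 1444 of the same genes.

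Among the 10 largest rises in heterozygous hearts were Zfp536 (3.65), Chrm2 (3.50), Lmbrd2 (3.40), Nt5c1a (3.35), Nebl (3.29), Eps8l1 (3.18), Slc9a7 (3.14), Hipk2 (3.07) and Samd5 (2.99). Hipk2, a nuclear protein kinase, reached 92.3 ± 7.02 CPM (SD, n = 3, adjusted p = 6.31e-06). The largest falls, beside Sln, were Cfd (-6.82), Susd5 (-4.52), Myl7 (-4.36), Cnn1 (-3.93), Wif1 (-3.36), Comp (-3.36), Inmt (-3.14), Myl4 (-3.01) and Ccdc3 (-2.97). Eps8l1 no longer passed without wild type 1 (4.25, adjusted p = 0.0611), wild type 2 (2.58, adjusted p = 0.234), heterozygous 1 (3.29, adjusted p = 0.0617), heterozygous 2 (2.42, adjusted p = 0.128) or homozygous 1 (3.18, adjusted p = 0.0613). Cfd was lost without wild type 2 (-4.26, adjusted p = 0.111), and Wif1 without wild type 1 (-2.15, adjusted p = 0.120), heterozygous 1 (-3.07, adjusted p = 0.0591) or heterozygous 2 (-3.03, adjusted p = 0.0670).

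Lists of lower genes in heterozygous hearts were again cytosolic ribosomal proteins, with 41 falls and 0 rises of 78 (alone 56 and 0, median -0.70, adjusted p = 2.46e-08, and adjusted p = 0.696 with an estimated correlation). Oxidative phosphorylation had 41 falls and 3 rises of 84 (alone 55 and 4, median -0.60, adjusted p = 2.46e-08, and adjusted p = 0.696 with an estimated correlation), and mitochondrial ribosomal proteins had 25 falls and 5 rises of 78 (alone 28 and 7, adjusted p = 0.000804, and adjusted p = 0.696 with an estimated correlation, without wild type 2 adjusted p = 0.0888). Of 39 interferon response genes 12 fell (alone 14, adjusted p = 0.0003, and adjusted p = 0.696 with an estimated correlation), with the immunoproteasome subunit Psmb9 at -1.80 (SE 0.31). Of 28 immediate early genes 8 fell (alone 9, adjusted p = 0.000804, and adjusted p = 0.627 with an estimated correlation), with the matricellular gene Cyr61 at -1.18 (SE 0.14). Of 44 matrix genes 11 fell (alone 11, adjusted p = 0.0328, and adjusted p = 0.696 with an estimated correlation), with the thrombospondin Thbs4 at -1.78 (SE 0.26). The list call was lost without heterozygous 3 or wild type 1 (adjusted p = 0.138 and 0.503), and without the latter the list's median was 0.11. Of 29 fetal and stress genes 9 fell and 3 rose (alone 9 and 3, adjusted p = 0.0374, and adjusted p = 0.627 with an estimated correlation, without heterozygous 3, wild type 1 or wild type 2 adjusted p = 0.0881, 0.156 and 0.0597). After the correction the call of mitochondrial ribosomal proteins (adjusted p = 0.586, median -0.03) and that of fetal and stress genes (adjusted p = 0.0659) were lost in heterozygous hearts. In that fit 13 cytosolic ribosomal protein genes and 10 oxidative phosphorylation genes fell (list tests adjusted p = 0.000177 and 0.0138, and adjusted p = 0.749 for each with an estimated correlation). Mitochondrial ribosomal proteins then had 11 falls and 4 rises, and 5 immediate early genes fell (adjusted p = 0.0138, and adjusted p = 0.642 with an estimated correlation).

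The lists given next did not pass in heterozygous hearts before the correction. After it, transcription factors, the TCA cycle and adult maturation passed upward (adjusted p = 0.00422 each, and adjusted p = 0.231, 0.749 and 0.391 with an estimated correlation). Transcription factors had 11 rises and 3 falls of 31 (alone 12 and 3, adjusted p = 0.0528, and 0.0158 and 0.0485 without heterozygous 1 or homozygous 1), with Prox1 at 1.64 (SE 0.19). The TCA cycle had 7 and 4 of 27 (alone 7 and 4, adjusted p = 0.340), with Pdha1 at 1.65 (SE 0.22). Adult maturation genes had 13 and 5 of 44 (alone 13 and 6, adjusted p = 0.203), with Ppp1r3a at 2.24 (SE 0.19). Calcium handling had 11 and 4 of 40 (alone 13 and 5, adjusted p = 0.226). Ion channels had 7 and 3 of 34 (alone 7 and 3, adjusted p = 0.374), and fatty acid oxidation 7 and 5 of 49 (alone 7 and 5, adjusted p = 0.9999, median -0.07, mean 0.04). Mitochondrial dynamics had 11 and 4 of 32 (alone 11 and 4, adjusted p = 0.203), and glycolysis 1 and 6 of 29 (alone 1 and 6, adjusted p = 0.207). After the correction glycolysis had 3 rises and 3 falls (median 0.05, list test adjusted p = 0.685). Thick filament genes had 6 and 6 of 21 (alone 6 and 7, adjusted p = 0.462), thin filament genes 6 and 6 of 22 (alone 6 and 9, adjusted p = 0.769) and Z-disc genes 10 and 7 of 47 (alone 11 and 8, adjusted p = 0.383), with Sgcd at 2.63 (SE 0.14). After the correction thick filament genes had 4 rises and 2 falls, thin filament genes 4 and 2, and Z-disc genes 8 and 2. Of the panel, Actn1 was at -0.63 (adjusted p = 0.00517) and Actn4 at -0.33 (adjusted p = 0.0922). Kcnj2 rose by 1.69 (adjusted p = 0.0186, 1.24 and 0.142 without wild type 2). Tnni3 was at -0.71 (adjusted p = 0.0230) and lost its call without wild type 2 (-0.25, adjusted p = 0.273) or heterozygous 1, 2 or 3 (-0.70, -0.74 and -0.65, adjusted p = 0.0520, 0.0599 and 0.0835). Myh6 (-0.39), Myh7 (-0.41), Nppa (-0.54), Nppb (-0.52), Acta1 (-0.96), Tnni1 (-3.40), Cacna1c (-0.10), Ppargc1a (1.04), Cpt1b (-0.02) and Pdk4 (0.87) did not pass. Myh7, Tnni1 and Cpt1b passed without wild type 1 (-0.61, -4.28 and 1.63, adjusted p = 0.0258, 0.0170 and 0.00786), and Acta1 and Ppargc1a without heterozygous 1 (-2.52 and 1.43, adjusted p = 0.000812 and 0.0295). The sign also changed without wild type 2 for Nppb (0.41) and Cacna1c (0.0334), and without heterozygous 1 for Cacna1c (0.0445) and Cpt1b (0.18).

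**Figure D3:**
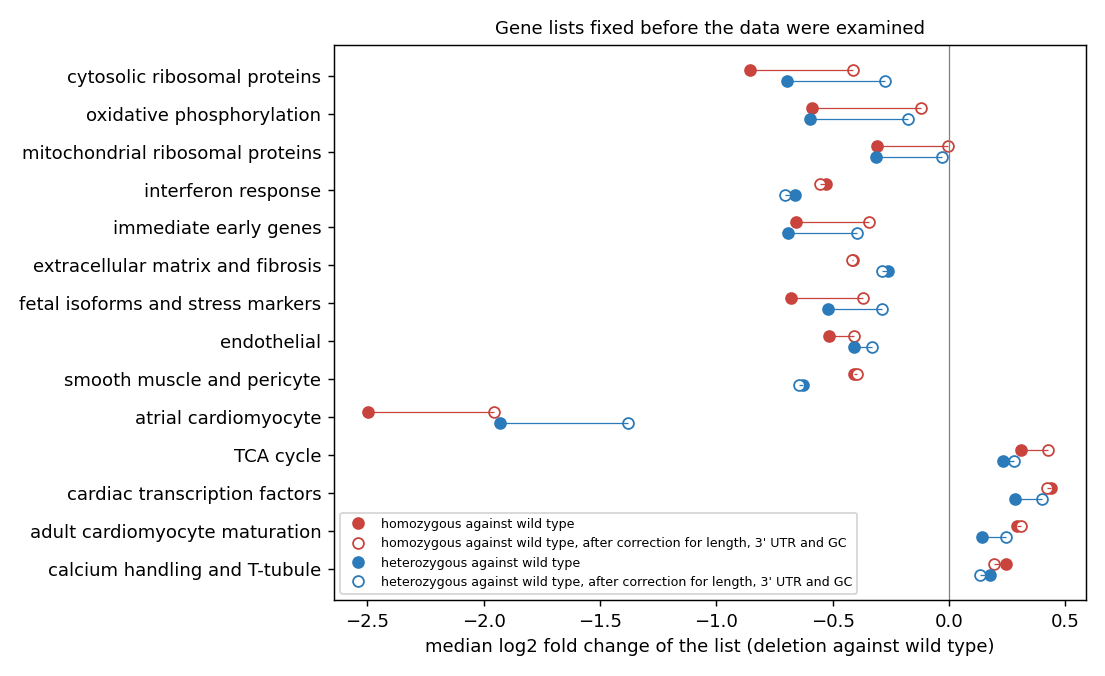
Median log2 fold change (x axis) of the lists that passed camera with the preset correlation against wild type before the correction, with adult maturation and calcium handling added. Other lists that passed only by fry or only after the correction are not drawn. Filled points are values before and open points after the correction for transcript length, 3' UTR length and GC content, in red for homozygous and blue for heterozygous hearts. The atrial median was -2.50 in homozygous hearts before and -1.95 after the correction.

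The list test fry, which sets each list against no change and not against the other genes, gave other calls. Atrial markers passed downward by it (adjusted p = 0.00191 in homozygous and 0.00194 in heterozygous hearts), as did fetal and stress genes (0.00224 and 0.00194) and immediate early genes (0.0249 and 0.0183). Adult maturation genes passed upward (0.00191 and 0.00211), as did calcium handling (0.00246 and 0.00669), transcription factors (0.00239 and 0.00669) and mitochondrial dynamics (0.0249 and 0.0347). Cytosolic ribosomal proteins (0.0882 and 0.132), oxidative phosphorylation (0.0899 and 0.0906) and mitochondrial ribosomal proteins (0.114 and 0.132) did not pass by fry. Matrix genes (0.119 and 0.208), interferon genes (0.197 and 0.132) and endothelial markers (0.0882 and 0.0906) did not either, nor did the TCA cycle in homozygous hearts (0.0882) or smooth muscle markers in heterozygous hearts (0.0906).

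Homozygous against heterozygous asks whether the second deleted copy adds to the first. No gene passed edgeR's quasi-likelihood test (0 of 15075), DESeq2 called 2 and limma-voom 0. At an unadjusted p under 0.05 there were 411 genes by edgeR, fewer than the 754 expected by chance, so the test was conservative here. In a fit of only the groups compared there were 741, and 0 passed after adjustment. The absence of calls is thus no sign that the second copy adds nothing. The smallest p-values were those of Irs2, the insulin receptor substrate, at 9.72 ± 1.26 CPM in wild type (SD, n = 2), 46.3 ± 9.84 CPM in heterozygous and 16.0 ± 2.85 CPM in homozygous hearts (SD, n = 3 each, log2 fold change -1.54, SE 0.19, adjusted p = 0.0922), and of Cyr61 at 79.2 ± 4.46, 35.0 ± 5.11 and 65.1 ± 3.72 CPM (0.90, SE 0.12, adjusted p = 0.165). Foxd3 (1.67), Spsb4 (0.76), Wisp1 (-1.10) and Hsp90aa1 (-0.46) followed. No list member passed over all genes; adjusted over the list alone, 4 immediate early genes were higher and 3 lower, and 1 heat shock gene was lower. TCA cycle and fatty acid oxidation genes passed upward by camera (adjusted p = 0.00346 and 0.00754) and cytosolic ribosomal proteins downward (adjusted p = 0.000385, median -0.15), and all had adjusted p = 0.888 with an estimated correlation and 0.915 by fry. The ribosomal call was lost without heterozygous 1 (adjusted p = 0.0566), the TCA call without homozygous 3 (0.0822), and the fatty acid call without heterozygous 2, heterozygous 3, homozygous 1 or homozygous 3 (0.367, 0.0581, 0.3601 and 0.158). Of the lists not called, several passed with 1 library left out. These were matrix genes without heterozygous 3 or homozygous 2 (0.00171 and 0.00446), interferon genes without heterozygous 1, homozygous 3, wild type 1 or wild type 2 (0.0303, 3.04e-05, 0.0472 and 0.0485) and oxidative phosphorylation without heterozygous 1 (0.0134). Others were fibroblast markers without heterozygous 3 or homozygous 2 (0.0448 and 0.00962), cell cycle genes without homozygous 1 or 3 (0.00422 and 0.0101). Further ones were heat shock genes and erythroid markers without homozygous 1 (0.00303 and 0.0200), and smooth muscle and macrophage markers without heterozygous 2 (0.0124 for each). After the correction, matrix genes passed downward (0.0149) and oxidative phosphorylation upward (0.0396), with adjusted p = 0.862 for each with an estimated correlation. Of all genes, 1 was called when homozygous 2 was left out.

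Both deletion genotypes moved the same genes relative to the same wild-type libraries. Of the genes called, 3479 were called in both genotypes in the same direction, 1996 higher and 1483 lower, and 0 in opposite directions. Fold changes correlated across genes at 0.886, with a covariance of 0.618. For comparison, 20 simulated pairs of unchanged groups set against shared wild-type libraries gave a mean correlation of 0.632 and a mean covariance of 0.145. This leaves a covariance difference of 0.473. The simulation gave each gene the same spread in all genotypes and no trend with gene properties. The real wild-type libraries differed more from each other than the deletion libraries did, and they followed such a trend. The covariance difference is therefore no measure of a shared effect of the deletion. With wild type 1 in one comparison and wild type 2 in the other the correlations were 0.462 and 0.420. Over the 4920 genes called in either genotype, homozygous fold changes were 0.933 times the heterozygous ones (0.878 to 0.980 leaving out each library), and 47.0% were larger in homozygous hearts. The mean of both deletion genotypes differed from wild type in 5086 genes, 2635 higher and 2451 lower. Without wild type 2 there were 2610, 1796 higher and 814 lower, and after the correction 2709, 1456 higher and 1253 lower. A slope on the number of deleted alleles passed for 0 genes by edgeR (4640 at an unadjusted p under 0.05), 2651 by DESeq2 and 0 by limma-voom.

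Fold changes against wild type followed the properties of the genes. Across genes, the Spearman correlation of the homozygous fold change was 0.406 with transcript length, 0.400 with 3' UTR length and -0.423 with GC content, and the heterozygous values were 0.382, 0.390 and -0.456; genes are not independent replicates. The median homozygous log2 fold change was -0.41 in the group of genes with the shortest 3' UTRs (group 1 of 5 by length) and 0.37 in the group with the longest. Splines of the 3 properties explained 16.9% and 17.9% of the deviation of wild type 1 and 2 from the mean library, and 3.996% to 9.44% in the deletion libraries. Short transcripts such as those of ribosomal proteins and long ones such as that of Ttn, titin, lay toward opposite ends of this trend. Ttn was at 0.83 and 0.76 in homozygous and heterozygous hearts, and at 0.13 and -0.18 after the correction.

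**Figure D4:**
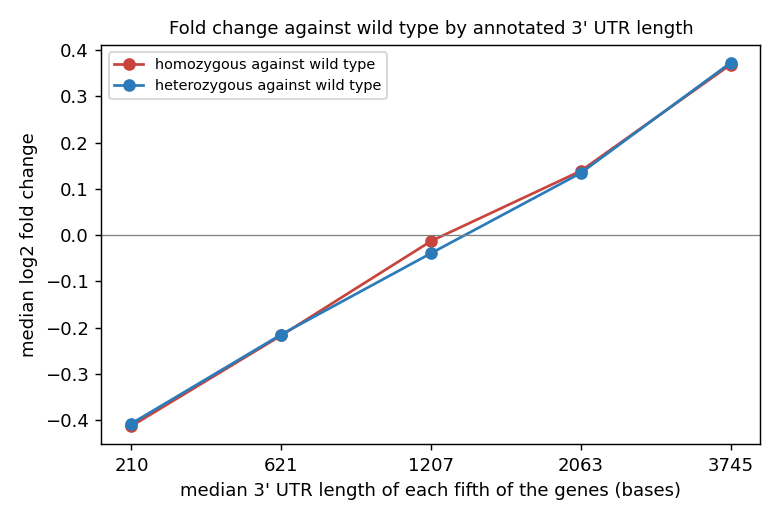
Median log2 fold change against wild type (y axis) in 5 groups of genes by annotated 3' UTR length (x axis, median length of each group in bases), with lines for homozygous and heterozygous hearts. The homozygous median ran from -0.41 to 0.37.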

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

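The tests, lists and first alternatives were fixed before the data were examined, and the correction for gene properties and its combinations were chosen after seeing the data. Scaling moved no count of calls by more than 1.5 times. For homozygous against wild type 4180 genes became 2564 without homozygous 3, 2135 without wild type 2, 1997 with the correction, 737 (551 higher, 186 lower) with the correction and without wild type 2, and 2098 with the correction and sex (2135 to 5717 leaving out each library). For heterozygous against wild type 4219 became 2668 with only the groups compared, 2359 without wild type 2, 1899 with the correction, 684 (500 higher, 184 lower) with it and without wild type 2, and 2362 with it and sex (2359 to 5634). For either deletion 5086 became 2610 without wild type 2, 2709 with the correction, 914 (636 higher, 278 lower) with it and without wild type 2, and 2982 with it and sex (2610 to 6180). Homozygous against heterozygous, 0 became 2 with no filter, 2 with DESeq2, 1 without homozygous 2, 1 at adjusted p under 0.1, and 2 with the correction without wild type 2 (0 to 1). For the trend 0 became 6 with no filter, 2651 with DESeq2 and 2843 at adjusted p under 0.1 (0 to 0). A fit of only the groups compared is not defined for either deletion or the trend. The overlap correlation of 0.886 became 0.462 and 0.420 with a different wild-type library in each comparison.

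Actn2 in heterozygous hearts, -0.59, was -0.59 with only the groups compared (adjusted p = 0.0536), -0.59 with the replicate block (0.0546), -0.27 with the correction (0.237), -0.15 with it and without wild type 2 (0.678), and -0.26 with it and sex (0.237). Leaving out each library gave -0.73 to -0.40. In homozygous hearts, -0.41 was -0.41 with DESeq2 (0.0375) and 0.0420 with the correction without wild type 2 (0.928), and leaving out each library gave -0.55 to -0.22. Homozygous against heterozygous gave 0.0650 to 0.262. The replicate block gave 3328, 3376, 4230, 0 and 0 calls for homozygous, heterozygous, either, homozygous against heterozygous and trend. Heterozygous and homozygous libraries of the same number correlated at r = 0.177, 0.138 and -0.0228 after the genotype means were removed, and the other pairs at -0.225 to 0.135. The same-number pairs with r above 0 also shared the Xist class and the remaining one did not. Pairing by number can thus neither be shown nor set aside.

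Of 215 named-gene results 172 kept their call and direction without wild type 2, 161 of 212 with the correction and 113 of 212 with both. Of 114 list results 90 were the same with an estimated correlation, which took all 24 calls, 90 by fry (17 calls lost, 7 gained) and 97 with the correction. The replicate block took 5 list calls (endothelial in both genotypes, adjusted p = 0.0915 and 0.0793, and fetal, matrix and smooth muscle in heterozygous hearts, 0.0616, 0.236 and 0.0728). It added 2 for homozygous against heterozygous (matrix 0.0322, interferon 0.0455). Reversed in homozygous hearts: Lgals8 (from 0.13) -0.0111 (correction) and Ero1lb (from 0.12) -0.24 (correction), -0.35 (correction without wild type 2), -0.26 (correction with sex), -0.0124 to 0.31 leaving out each library (reversed without wild type 2). Nid1 (from 0.48) -0.0867 (correction without wild type 2) and Chrm3 (from 0.18) -0.00607 (correction without wild type 2). Nppb (from -0.18) 0.22 (correction), 0.84 (correction without wild type 2), 0.16 (correction with sex), -0.73 to 0.75 leaving out each library (reversed without homozygous 2 and without wild type 2) and Tnni3 (from -0.76) 0.0738 (correction without wild type 2). Cacna1c (from -0.0765) -0.17 to 0.0592 leaving out each library (reversed without wild type 2) and Cpt1b (from 0.56) -0.16 to 2.21 leaving out each library (reversed without wild type 2). Pdk4 (from 0.70) -0.14 (correction without wild type 2) and Ddx3y (from 1.18) -0.0363 (sex term), -0.32 (correction without wild type 2), -0.70 (correction with sex). Cd3d (from -2.89) 4.17 (correction without wild type 2), -6.85 to 4.14 leaving out each library (reversed without wild type 2) and Cidea (from -0.93) 0.11 (correction without wild type 2). Cd3d had 0 and 28 counts in wild type 1 and 2, and 0, 9 and 0 in homozygous 1 to 3. Without wild type 2 the wild type had no Cd3d count, and without homozygous 2 the homozygous group had none. No floor was set here, so these Cd3d values and their reversal are not measured changes. Tnnt3 (from -1.47) 1.44 (correction without wild type 2), -2.33 to 1.12 leaving out each library (reversed without wild type 2) and Ager (from -0.82) 0.71 (correction without wild type 2), 0.10 (correction with sex), -1.41 to 0.26 leaving out each library (reversed without wild type 2). Reversed in heterozygous hearts: Heatr1 (from 0.00260) -0.00882 (1 CPM filter), -0.00424 (limma-voom), -0.36 (correction), -0.26 (correction without wild type 2), -0.35 (correction with sex), -0.0438 to 0.0865 leaving out each library (reversed without heterozygous 2 and without wild type 1) and Lgals8 (from 0.13) -0.0381 (correction), -0.0475 (correction with sex). Ero1lb (from 0.0164) -0.0537 (replicate block), -0.37 (correction), -0.47 (correction without wild type 2), -0.34 (correction with sex), -0.12 to 0.21 leaving out each library (reversed without heterozygous 3 and without wild type 2) and Nid1 (from 0.41) -0.11 (correction without wild type 2). Nppa (from -0.54) 0.0794 (correction), 0.33 (correction without wild type 2), 0.0560 (correction with sex) and Nppb (from -0.52) 0.44 (correction without wild type 2), -1.06 to 0.41 leaving out each library (reversed without wild type 2). Tnni3 (from -0.71) 0.11 (correction without wild type 2) and Cacna1c (from -0.10) -0.19 to 0.0445 leaving out each library (reversed without heterozygous 1 and without wild type 2). Cpt1b (from -0.0205) 0.48 (limma-voom), 0.17 (replicate block), 0.28 (sex term), 0.23 (correction), 0.53 (correction with sex), -0.74 to 1.63 leaving out each library (reversed without heterozygous 1 and without wild type 1) and Ttn (from 0.76) -0.18 (correction), -0.15 (correction without wild type 2), -0.17 (correction with sex). Tnnt3 (from -1.997) 0.88 (correction without wild type 2), -2.86 to 0.60 leaving out each library (reversed without wild type 2) and Ager (from -0.72) 0.83 (correction without wild type 2), -1.53 to 0.36 leaving out each library (reversed without wild type 2). Of these, Tnni3 in both, Cidea and Ttn had been called. The cause was not tested.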

Other observations

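Of the tests given here, the correction's share of kept calls and its effect on Actn2 were set down before their results were seen; the test of calls left after the correction, those of wild type 2, of the slope, of the splits, of Actn2 between the deletion genotypes and of the atrial markers were chosen only after the result was seen. Among clock genes, Rora, which activates Bmal1 transcription, rose by 1.41 in log2 units in homozygous and 1.44 in heterozygous hearts (SE 0.15 each), and Clock by 1.01 and 1.14 (SE 0.13 each). After the correction Rora was at 0.53 and 0.52 and Clock at 0.18 and 0.28, and only Rora passed. Of 20 clock genes 3 rose and 4 fell in homozygous hearts (adjusted over the list alone 3 and 4; adjusted p = 0.944) and 2 rose and 0 fell in heterozygous hearts (alone 2 and 0; adjusted p = 0.994, with a median of -0.09, a mean of 0.01 and a test pointing down). Stress lists were mixed before the correction: of 23 heat shock genes 5 rose and 4 fell in homozygous hearts (alone 5 and 5, adjusted p = 0.916) and 7 rose and 4 fell in heterozygous hearts (alone 7 and 5, adjusted p = 0.769). After it, 4 heat shock genes rose and 0 fell in each genotype (list test adjusted p = 0.267 in homozygous and 0.0669 in heterozygous hearts). Hsp90aa1, a cytosolic chaperone, was at 178 ± 4.78 CPM in wild type, 370.0 ± 15.5 CPM in heterozygous and 269 ± 15.9 CPM in homozygous hearts. Of 30 genes of the integrated stress and unfolded protein response 2 rose and 5 fell in homozygous hearts (alone 2 and 5, adjusted p = 0.216), and 2 rose and 6 fell in heterozygous hearts (alone 2 and 6, adjusted p = 0.203). With the correction 2 of these rose and 1 fell in homozygous hearts, and 1 rose and 1 fell in heterozygous hearts (medians 0.00582 and -0.0523).

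Of 45 cell cycle genes 1 rose and 1 fell in homozygous hearts, and 2 rose and 1 fell in heterozygous hearts (alone 0 and 0 in each; adjusted p = 0.916 and 0.971). Of 6 sex-linked genes 0 passed in each comparison with wild type (alone 0; adjusted p = 0.903 and 0.9999), with means of 0.99 and 0.77 in log2 units and an unequal share of Xist-high libraries per genotype. The heterozygous median was 0.27, while its test pointed down. After the correction, TCA cycle genes had 11 rises and 0 falls of 27 in homozygous hearts and 5 rises and 0 falls in heterozygous hearts (adjusted p = 6.99e-06 and 0.00422, and adjusted p = 0.531 and 0.749 with an estimated correlation). Adult maturation genes had 13 rises and 1 fall of 44, and 11 rises and 1 fall (adjusted p = 0.000981 and 0.00422, and adjusted p = 0.267 and 0.391 with an estimated correlation).

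The genes differing between wild type and both deletion genotypes were 3479 in number, and part of this may reflect transcript length, 3' UTR length and GC content weighed differently in the wild-type libraries: 40.1% of the calls for either deletion were kept by the correction. The trend removed by the correction did not account for all of it. The corrected fit called 19.1% of its genes (2709 of 14171), and 1990 of these had been called in the same direction before it. Effects of the properties beyond that trend were not tested. With wild type 2 left out as well, in a fit with 1 wild-type library, the count was lower still. Without the outlying library wild type 2, 51.1% as many genes were called for homozygous hearts, in a fit with 1 wild-type library and spread from the deletion groups alone, so its part in the pattern stays open. The slope of 0.933 gave no sign of a response graded by allele number. Both fold changes share the wild-type libraries, however, and an offset of these libraries alone would pull the slope toward 1. A graded response therefore stays open. Of the 28 ways to take 2 of the 8 libraries as wild type, 1, the real one, gave as many calls (5338, highest other 3). Every other pick leaves a wild-type library among the rest, which widens the spread there and can itself lower the calls. The splits therefore cannot set chance aside. An unlabelled difference in how the wild-type hearts were handled would fall on the same libraries as genotype, so it stays open beside the deletion itself.

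Actn2 had lower values in both deletion genotypes and passed only in heterozygous hearts. The correction left it at -0.272 in heterozygous hearts and -0.08 in homozygous hearts (0.0420 with wild type 2 left out as well), and the heterozygous value lay between the bounds set for and against the gene properties as the cause, so that the deletion and these properties cannot be told apart for this gene. Its annotated 3' UTR of 71 bases limits what the correction can say about it. A loss graded by allele number would put homozygous below heterozygous hearts, and the difference was 0.178 (SE 0.14), which leaves this open.

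Atrial markers were lower in both deletion genotypes. The correction moved their median from -2.50 to -1.95 in homozygous and from -1.93 to -1.38 in heterozygous hearts. The trend it removes thus did not account for the whole fall. It is an average over genes, and effects of the gene properties beyond it were not tested. Atrial tissue included to a different extent in each wild-type sample could account for the lower atrial markers. The ratio of wild type 2 to wild type 1 above the deletion libraries was 2.28 for Myl4, 2.23 for Myl7, 1.80 for Sln, 4.23 for Stard10 and 1.14 for Dkk3. This 3.70-fold range lay between the bounds set. Its upper end rests on Stard10, at 21.9 CPM in wild type 1 and 16.9 CPM on average in the deletion libraries. The Stard10 ratio thus divides by a small remainder. These ratios compare the wild-type hearts only and cannot say whether the deletion samples held less atrial tissue. That explanation therefore stays open.

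For homozygous against heterozygous hearts, the real count was 0, which all 10 splits of the 6 libraries into 3 and 3 reach whatever the data (highest other 3), so the splits cannot say anything about this comparison.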
